A study of Homo sapiens with 2 samples.

How the data were processed

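Chromatin of MDA-MB-231 cells transduced with lentiviral CRISPRi was sheared with an enzyme, and dCas9-bound DNA was isolated with an antibody against dCas9, per the labels' protocols. Libraries followed Illumina's TruSeq ChIP protocol, per the labels. The groups were taken from the treatment label, with 1 library for the copGFP control guide and 1 for the guide to KLF2 binding site 1 of the miR-125b-1 promoter. No input library was used in peak calling, per the file headers.

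Reads were processed with FastQC, Trimmomatic and Bowtie, with hg19 as the genome build, per the submitters' processing notes, which give no order or parameters. Peaks were called per library with MACS 2.1.1.20160309 on paired-end fragments, with a q threshold of 0.01, 1 fragment kept per position, summits called within peaks and a local background window of 10000 bp, per the file headers. The headers gave 10203621 fragments after duplicate removal and a fragment size of 163 bp for the control library, and 7504992 fragments and 159 bp for the targeted library. The deposited pileup is a coverage signal, the number of deduplicated fragments over a summit, and it was not scaled to depth. The deposited fold enrichment is a ratio of pileup to the local background of the same library. The −log10 p-value and −log10 q-value of each peak are those the authors' peak caller gave against that background. Annotation of peaks to genes was made with ChIPseeker, per the submitters' processing notes. The authors' comparative table holds deposited counts of raw reads per peak in each library, per its column names. It also holds the authors' rescaled log2 ratio of those reads (targeted over control), their mean log2 level, and a −log10 p-value for the 2 libraries. How the reads were counted, rescaled and tested is not given in the sources used here. The log2 raw read ratio with 1 added to each count exceeded the authors' rescaled log2 ratio by a median of 0.17 (0.02 to 0.26). Other deposited values were positions, widths and distances to the nearest transcription start, as the authors wrote them.

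Because duplicates were removed before peak calling but raw reads were counted per peak, reads and pileup measure different things. Removal of duplicates limits the height of a peak. Raw reads may repeat molecules, though whether duplicates were counted is not given. Local background from the same library raises or lowers the fold enrichment of a peak with the coverage around it. Reads from repeats can be placed at the wrong copy, and how such reads were treated is not given in the sources used here.

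Positions were written 1-based. Summits in 1 MACS interval were merged into 1 peak with the values of its highest summit, so that 95 control summits gave 62 peaks and 97 targeted summits gave 78. Of these, 53 and 74 were nuclear, and 9 and 4 mitochondrial. The authors' table held no mitochondrial peaks, so read counts cover nuclear peaks. All 156 entries of that table equalled the MACS tables in position, pileup and fold enrichment. Peaks were shared where they overlapped by at least 1 bp (bedtools 2.31.1), and the nuclear library-only peaks were the same 14 and 35 as in the authors' deposited lists. Summaries were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots with matplotlib 3.10.9. The overlap and ratio code was tested for the overlap comparison on 134 simulated regions, where it recovered all 40 shared and all 24 and 30 library-only regions and a median log2 ratio of 0.50 for a simulated 0.5.

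Shares were given exact Clopper-Pearson intervals, and read ratios exact conditional binomial intervals, all at 95%. Intervals on shares take peaks as independent and are too narrow where peaks cluster. A ratio against 0 reads was given with the 0 set to a floor of 3 reads per library, beside the exact lower limit against 0. Raw read ratios were not scaled for depth, except where stated. With 1 library per group no test of the conditions was made. The 2-fold level on the authors' rescaled ratio was chosen after the data were examined.

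The named peaks followed a rule fixed before the data were examined. It took every peak at the 8 genes of the miR-125b-1 locus, the 10 highest by fold enrichment in each library, the 10 highest library-only peaks in each library, and the 5 highest and 5 lowest ratios of fold enrichment at shared loci. It also took every peak at 12 genes with promoters common in lentiviral vectors, and counted peaks at 12 KLF2 targets, 26 miR-125b targets and 59 genes beside repeats. Other peaks were named after their values were seen. Symbols of overlapped genes came from Entrez identifiers, of which 13 of 13 matched a gene table on assembly GRCh38, used for names and neighbours only. In that table MIR125B1 lies within MIR100HG. The distance of the peak to the miR-125b-1 hairpin and the match of the guide to any peak were not analysed here, since no hg19 sequence or annotation and no guide sequence were used.

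Alternatives covered stricter thresholds (−log10 q or fold enrichment of at least 10), chromosomes 1 to 22 and X only, other definitions of overlap, pileup or reads in place of fold enrichment, and other scalings of the read ratio.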

Results

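The binding of dCas9 to chromatin was profiled by ChIP-seq in MDA-MB-231, an established human triple-negative breast cancer cell line. dCas9 is a catalytically inactive Cas9 that a guide RNA brings to a matching DNA sequence without cutting it, and CRISPRi uses it to block transcription or the binding of other factors. The control library came from cells whose guide was directed at copGFP, a reporter sequence that is not part of the human genome. The targeted library came from cells whose guide was directed at binding site 1 of the transcription factor KLF2 in the promoter of miR-125b-1, a microRNA gene. Each group had 1 library, from cells at passages 23 to 25, so there were no replicates and no test of the conditions. The control library held 10203621 deduplicated fragments and the targeted library 7504992, a ratio of 0.736. The fold enrichment, pileup and q of each peak were the authors' own values, and positions are given in hg19.

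The study's main comparison asked whether dCas9 was found at the guide's target. The targeted library had 1 peak at the miR-125b-1 locus and the control library had 0. The peak lay on chromosome 11 from 121971052 to 121971217, with its summit at 121971090, and was assigned to MIR100HG, the host gene of the miR-100, let-7a-2 and miR-125b-1 microRNAs. The annotation placed it at a promoter, at a distance of 0 bp from the start of a MIR100HG transcript. Its 166 bp held 129 raw reads in the targeted library and 1 in the control library, a raw ratio of 129 with an exact 95% interval of 22.7 to 5134. In the authors' deposited table the rescaled log2 read ratio of this peak was 5.83 and its −log10 p, which compares the 2 libraries and not the conditions, was 32.1.

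By height the MIR100HG peak was among the weakest of the targeted library. Its summit was covered by 10 distinct fragments, its fold enrichment over the local background was 5.37, and its −log10 q was 2.71. By fold enrichment it had rank 69 of the 78 peaks of the targeted library and rank 35 of the 35 peaks found only there. By the rescaled log2 read ratio of the authors' deposited table it had rank 6 of those 35. The peak passed the authors' q threshold of 0.01 and was lost at a −log10 q of at least 3. Intervals on raw read ratios, here and below, take every read as independent. They are too narrow where PCR copies of a molecule were counted, and they do not cover variation between libraries. With the 10 distinct fragments set against the 1 raw control read and scaled for depth, the ratio was 13.6 (exact 95% interval 1.93 to 590.0).

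The comparison of the peak lists then asked where else peaks were called with the miR-125b-1 guide. Of 97 loci in the union of both lists, 42 were shared, 20 were found only in the control library and 35 only in the targeted library. The 35 targeted-only peaks lay on 16 chromosomes, and 28 of them held at least 2-fold more reads in the targeted library by the rescaled log2 ratio of the authors' deposited table. Those 28 peaks had a median of 158 raw reads in the targeted library (34 to 563) and 6.5 in the control library (0 to 23). The median rescaled log2 ratio of the 28 in the authors' deposited table was 4.58 (1.89 to 7.48).

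The highest fold enrichment among the targeted-only peaks, 17.4, was on chromosome 12 from 81189522 to 81189709, in exon 1 of a transcript with 1 exon, at 36699 bp from the microRNA gene MIR617. It held 563 raw reads against 15 in the control library, a ratio of 37.5 (exact 95% interval 22.6 to 67.5). Near the promoter of TRIM39, which encodes an E3 ubiquitin ligase, the peak on chromosome 6 from 30295161 to 30295351 had a fold enrichment of 11.3. It held 202 raw reads against 0, a ratio of 67.3 when the 0 is set to the floor of 3 reads per library. The exact 95% lower limit of the ratio against 0 reads was 54.3. A peak 2772 bp from the start of IL5, a cytokine gene, lay on chromosome 5 from 131881986 to 131882191 with a fold enrichment of 10.9. Its 337 raw reads against 10 gave a ratio of 33.7 (18.1 to 70.9). The intergenic peak nearest to GPR26, an orphan receptor gene, lay on chromosome 10 from 125343489 to 125343696 and held 223 raw reads against 3, a ratio of 74.3 (25.1 to 363). The peak assigned to TRIM32 lay in intron 8 of 20 of ASTN2, on chromosome 9 from 119490450 to 119490645, with 238 raw reads against 13, a ratio of 18.3 (10.5 to 34.9). The peak assigned to SNX16, at 576599 bp from its start, lay on chromosome 8 from 83331120 to 83331305 with 328 raw reads against 4, a ratio of 82.0 (31.7 to 303). The peak assigned to CENPW, a centromere protein gene, lay on chromosome 6 from 126569557 to 126569740 with 202 raw reads against 16, a ratio of 12.6 (7.59 to 22.5).

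Peaks with 0 control reads, named after their values were seen, also lay in intron 1 of 7 of KAZN, in intron 8 of 10 of the inflammasome gene NLRP3, and at 833263 bp from SOX9. They held 105, 158 and 141 raw reads in the targeted library, ratios of 35.0, 52.7 and 47.0 with the same floor. The exact 95% lower limits against 0 reads were 28.0, 42.3 and 37.7. With distinct targeted fragments scaled for depth, the lower limits were 7.08 at TRIM39 and 3.78, 3.41 and 4.14 at these 3 peaks. Besides MIR100HG, TRIM39 and IL5, the promoter class of the 28 peaks held NNMT, KCNC4 and MLLT6. NNMT encodes nicotinamide N-methyltransferase, and its peak, 496 bp from the start, held 89 raw reads against 9. KCNC4 encodes a potassium channel, and its peak held 209 against 11, while the peak of MLLT6, 403 bp from the start, held 132 against 12. Introns of the chromatin remodelling genes ARID1B and SS18L1 and of the kinase gene MAPK9 held 135, 106 and 155 raw reads against 11, 1 and 10.

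The other 7 targeted-only peaks differed by less than 2-fold in reads. The largest by reads, named after its values were seen, was assigned to ANKRD26P1, 134944 bp from its start (chromosome 16, 46416816 to 46417368). It held 312 raw reads against 199, a ratio of 1.57 (exact 95% interval 1.31 to 1.88). Among the others were the peaks assigned to SULF1 (chromosome 8, 70602313 to 70602489, in intron 4 of 7 of SLCO5A1), with 35 raw reads in each library, and to PIK3AP1 (chromosome 10, 98510137 to 98510425), with 35 against 25. The peak assigned to POTEA on chromosome 8, from 43793846 to 43794009, held 71 raw reads against 44 (1.61, 1.09 to 2.41). The peak assigned to SPIN4 held 72 against 44 (1.64, 1.11 to 2.44). The rescaled log2 ratios of the 7 in the authors' deposited table ran from −0.24 to 0.48. Distinct fragments were then set in place of raw reads in the targeted library, and all raw reads of the control library were kept. The ratio was scaled by deduplicated fragments, which raises it. Of the 28 peaks, 16 had an interval above 1, among them MIR100HG, MIR617, TRIM39, IL5, GPR26, TRIM32 and SNX16. The lower limits at TRIM32 (1.05) and SYN2 (1.18) would not lie above 1 without that scaling. The 12 peaks without an interval above 1 were KCNC4, NNMT, MIR4308, MLLT6, PPP1R21, GPD1L, FGF12, CCSER1, MAPK9, CENPW (1.78, 0.887 to 3.66), ARID1B and ZFAT.

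**Figure D1:**
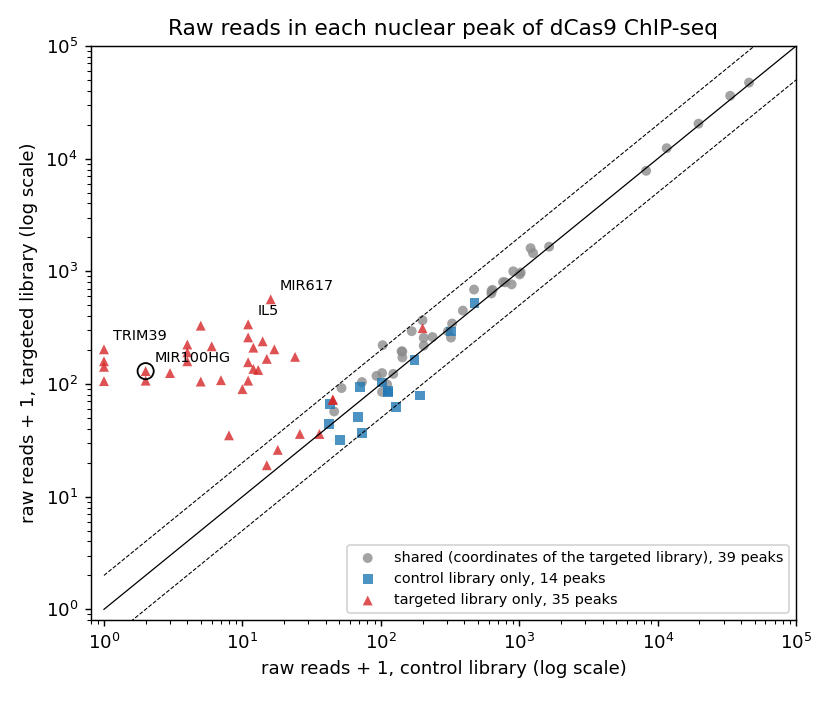
Raw reads in each nuclear peak, control library on the x axis and targeted library on the y axis, both on log scales with 1 added. Each point is a peak, the solid line marks equal reads, the dashed lines mark 2-fold differences, and the circle marks MIR100HG at 129 against 1 reads; 38 of the 39 shared peaks (grey) and 12 of the 14 control-only peaks (blue) lie between the dashed lines, and 28 of the 35 targeted-only peaks (red) lie above the upper one.

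The shared loci show where peaks were called with either guide. No input library was used, so dCas9 binding was not separated from background there. Of the 42, 39 were nuclear and 3 mitochondrial, and 36 of the 39 nuclear loci were annotated as distal intergenic (92.3%, exact 95% interval 79.1 to 98.4). They lay on 11 chromosomes. The peaks assigned to the pseudogene ACTR3BP2 on chromosome 2, to LOC441666 on chromosome 10 and to the pseudogene ANKRD26P1 on chromosome 16 made up 5, 8 and 7 of the loci. Within 100 kb of 33 of the 39 (84.6%, 69.5 to 94.1) lay another peak of the targeted library, against 2 of the 35 targeted-only peaks (5.71%, 0.700 to 19.2). Of the 14 nuclear control-only peaks, 10 (71.4%, 41.9 to 91.6) had another control peak within 100 kb. Intervals on shares, here and below, take peaks as independent. Peaks in 1 cluster are not, and each counts as the neighbour of the other, so these intervals are too narrow.

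The highest fold enrichments of both libraries lay almost entirely in this shared set. Peaks carry the name of the gene with the nearest start and need not lie in it. In the targeted library the shared peaks lay a median of 265.6 kb from that start. In the control library the highest was 23.0, at ACTR3BP2 (chromosome 2, 92307248 to 92307496), where the targeted library had 18.3. In the targeted library the highest was 22.6, at LOC441666 (chromosome 10, 42596914 to 42597196), where the control library had 20.0. Other ACTR3BP2 peaks had 20.6 and 18.5 in the control library and 22.2 and 19.1 in the targeted library. A peak assigned to the embigin pseudogene EMBP1 (chromosome 1, 121484399 to 121485423) lay 177975 bp from its start. The values there were 16.6 in the control and 18.0 in the targeted library, with 33341 and 36102 raw reads. Peaks assigned to SPIN4 on chromosome X, 851336 and 858453 bp from its start in the control library, had 16.2 and 15.4 there. The same loci had 12.1 and 15.4 in the targeted library. The peak in intron 35 of 38 of HFM1, a meiotic DNA helicase gene, had 14.8 and 15.0. Further LOC441666 peaks had 16.6 and 13.7 in the control and 14.7 and 15.0 in the targeted library. The MIR617 peak, at 17.4, was the only targeted-only peak among the 10 highest of its library.

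**Figure D2:**
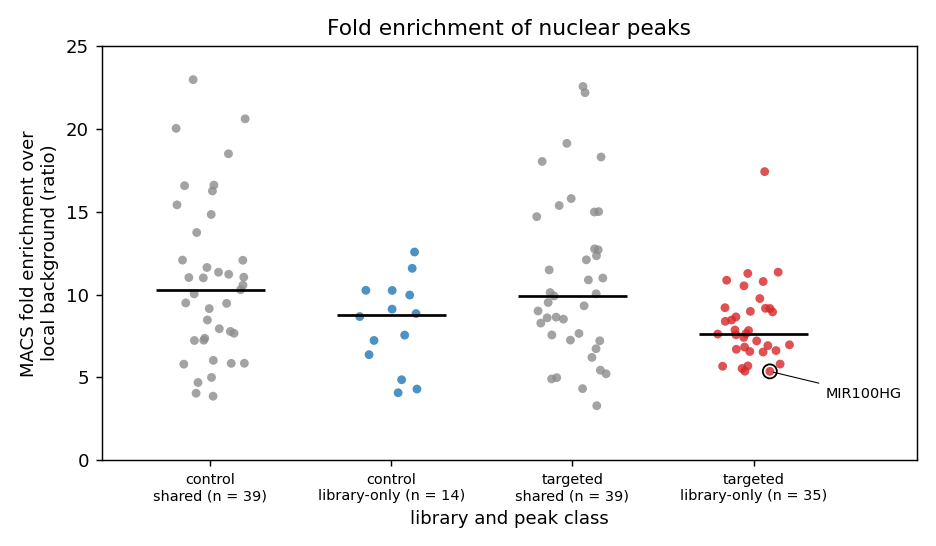
Fold enrichment over the local background (y axis, a ratio) of each nuclear peak by library and peak class (x axis), with horizontal bars at the medians. The medians are 10.3 and 9.92 for the shared peaks of the control and targeted libraries, 8.76 for the 14 control-only and 7.65 for the 35 targeted-only peaks, and the circle marks MIR100HG at 5.37.

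By fold enrichment the libraries differed little at the shared loci. The ratio of fold enrichment, targeted over control, had a median of 1.02 (0.744 to 1.43), a median log2 ratio of 0.02 with an SD of 0.20 across loci, and was above 1 at 22 loci and below 1 at 20. Raw reads, by contrast, were higher in the targeted library at 30 and lower at 8 of the 39 nuclear loci, and unscaled pileup was higher at 2 and lower at 38 of the 42. The lowest ratios were at SPIN4 (0.744 and 0.828), ANKRD26P1 (0.781), ACTR3BP2 (0.797) and LINC00293 (0.839). The highest were at LINC00662 (1.43), IRS4 (1.36), ANKRD26P1 (1.29), mitochondrial DNA from 1261 to 3972 (1.27) and LOC441666 (1.19). Across the 39 nuclear loci the log2 fold enrichments of the libraries had a Pearson r of 0.953 and a Spearman rho of 0.940, which describe peaks and not replicates. Each fold enrichment is relative to the background of its own library, and unscaled pileup gave a median log2 ratio of −0.43 at the depth ratio of 0.736. Raw reads at the 39 nuclear loci had a median ratio of 1.07 (0.804 to 2.15).

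The control-only peaks show signal called with the copGFP guide alone. They comprised 14 nuclear and 6 mitochondrial peaks, and 13 of the 14 were distal intergenic. The 14 lay a median of 230.2 kb from the nearest gene start. The highest fold enrichment, 12.6, was at a peak assigned to EMB, the embigin gene (chromosome 5, 49410189 to 49410367), with 127 raw reads in the control library and 62 in the targeted library. Further EMB peaks had 10.3 and 7.56, and POTEA (chromosome 8, 43827954 to 43828115) had 11.6 with 41 control and 43 targeted reads. The 1 promoter peak, at the pseudogene ROCK1P1 (chromosome 18, 108140 to 108303), had 10.3 with 67 control and 50 targeted reads. MTRNR2L1 had 9.12 and 8.86, a peak on chromosome 1 from 143283659 to 143283840 had 8.67, and ANKRD26P1 had 7.23. By the ratios of the authors' deposited table, 3 of the 14 held at least 2-fold more reads in the control library, at ACTR3BP2 (rescaled log2 ratio −1.49), EMB (−1.24) and FRG1JP (−1.22). ACTR3BP2 (chromosome 2, 92291399 to 92291611) had a fold enrichment of 9.97 and held 190 control and 78 targeted reads, and FRG1JP held 72 and 36. With raw reads scaled by deduplicated fragments, of which the control library had more, 0 of the 14 held at least 2-fold more in the control library. That scaling moves every ratio towards the targeted library, also at the shared nuclear loci, where the unscaled median was already 1.07. In the authors' deposited table the median rescaled log2 ratio of the 14 was −0.46, and 10 of them lay within the range of the control library's shared peaks (−0.83 to 0.83).

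**Figure D3:**
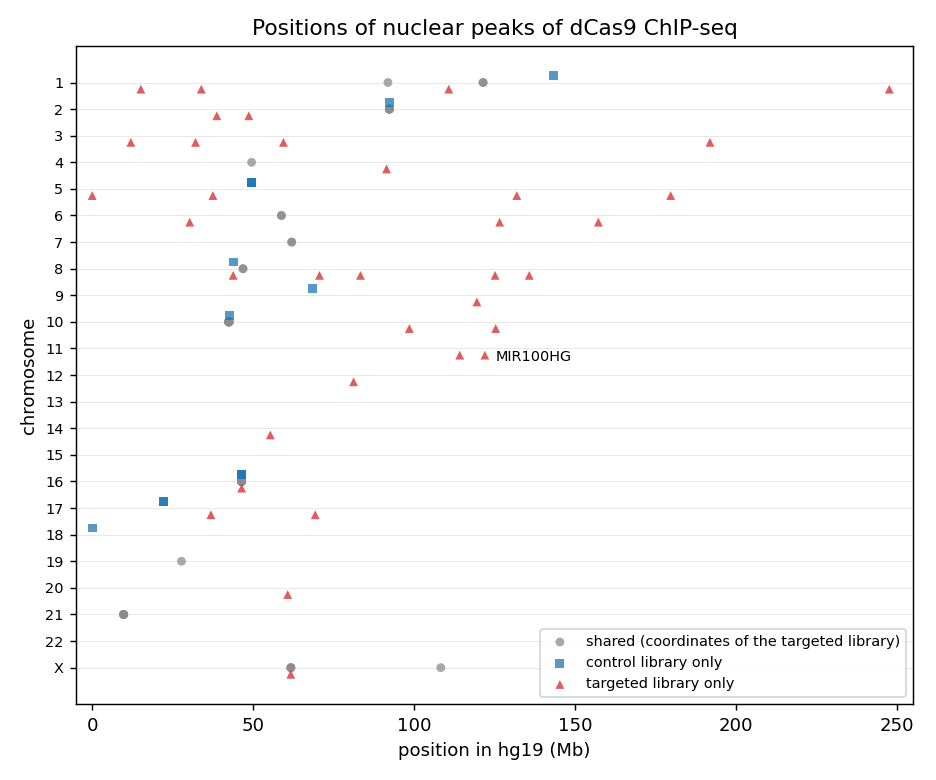
Positions of the nuclear peaks along each chromosome (x axis, hg19 position in Mb; y axis, chromosome), with control-only peaks drawn slightly above and targeted-only peaks slightly below their chromosome's line. The 39 shared peaks overlap in a few clusters on 11 chromosomes, while the 35 targeted-only peaks are spread over 16.

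Annotation classes and gene lists chosen before the data were examined describe what the peaks lay beside. Promoters held 8 of the 74 nuclear peaks of the targeted library (10.8%, exact 95% interval 4.78 to 20.2) and 3 of the 53 of the control library (5.66%, 1.18 to 15.7). Introns held 13 of the 74 peaks (17.6%, 9.70 to 28.2) against 1 of the 53 (1.89%, 0.0478 to 10.1), and distal intergenic sequence 70.3% (58.5 to 80.3) against 92.5% (81.8 to 97.9). Of the 8 genes of the miR-125b-1 locus, MIR100HG alone had a peak, in the targeted library. The 12 genes whose promoters are common in lentiviral vectors, such as EEF1A1 and PGK1, had 0 peaks in either library. The 12 known targets of KLF2, such as NOS3 and THBD, and the 26 known targets of miR-125b, such as BAK1 and ERBB2, also had 0 in either library. Peaks were counted by the gene assigned to them. No share over all genes was computed, so these counts of 0 do not set the lists apart from other genes. Of 59 genes beside repeats or known high-signal regions, ANKRD26P1, MIR3648-1 and MIR3687-1 had peaks in both libraries and ROCK1P1 in the control library. They accounted for 15 peaks of the control and 12 of the targeted library, 11 of them shared in each. These counts rest on gene names and not on repeat sequence, which the deposited data do not mark. Shared peaks assigned to genes outside the list, such as LOC441666 and ACTR3BP2, may lie in repeats too, so 11 is not a count of all shared peaks in repeats.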

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

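Alternatives for counts of peaks, overlap classes, annotation shares and vector promoters, and unscaled pileup or median centring at shared loci, were planned before the data were examined. Counts of summits, thresholds at the miR-125b-1 locus, read ratio settings, pileup scaled by depth, raw reads, and shared loci without mitochondrial DNA were chosen after the data were seen. Of 46 alternatives for 14 results, 30 left the value within its limits (1.5 times for a count) and 16 moved it. The count of reversed results was 0, though unscaled pileup, counted as moved, changed the sign of the median log2 ratio at shared loci. A fold enrichment of at least 10 left 25 of 62 control peaks, 25 of 78 targeted peaks, 4 of 20 control-only peaks and 6 of 35 targeted-only peaks. A −log10 q of at least 10 left 49 targeted and 11 targeted-only peaks. Counting every summit gave 95 in the control library. These changes follow from what each setting counts. The peak at the miR-125b-1 locus was lost (0 peaks) at a −log10 q of at least 3, at 10, and at a fold enrichment of at least 10. The 28 targeted-only peaks with at least 2-fold more reads became 27, 28, 31 and 23 under other read ratio settings. The 23 are of the 24 with a p in the authors' table, which gives none for the 4 with 0 control reads. With distinct fragments, scaled for depth, set against all raw control reads, 16 of the 28 had an interval above 1. The 3 control-only peaks with at least 2-fold more reads became 0 at a log2 ratio of at least 2 and 0 with scaling by deduplicated fragments. They became 1 with the authors' −log10 p of at least 10, and 0 with distinct fragments, scaled for depth, set against all raw reads of the other library. Raw reads outnumber distinct fragments, so that last setting lowers every ratio by construction. Scaling raw reads by deduplicated fragments raises every targeted over control ratio by the same factor, so it favours the targeted library by construction. A higher ratio limit or an added p limit can only lower a count. The median log2 ratio of fold enrichment at shared loci, 0.02, was −0.43 for unscaled pileup, 0.07 with each library divided by its median, and 0.01 for pileup scaled by deduplicated fragments. No paired analysis was possible because each group had 1 library. The planned search within 100 kb of the miR-125b-1 gene was not run, since no hg19 annotation was used. The −log10 q of 2.71 at MIR100HG leaves little margin above the threshold. Its pileup of 10 alone does not set that margin, since MLLT6 and ZFAT, with the same pileup, had 4.50 and 4.55.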

Other observations

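The tests below were all chosen after the patterns were seen, and no pattern has a replicate.

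Mitochondrial DNA held 9 peaks covering 7354 bp in the control library and 4 covering 1925 bp in the targeted library. At the 3 shared mitochondrial loci the pileup, scaled by deduplicated fragments, had targeted over control ratios of 0.321, 0.364 and 0.409, below the range of the 39 nuclear shared loci (0.704 to 1.89). Fold enrichment over the local background at the same 3 loci had a median ratio of 1.05 (0.922 to 1.27).

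The first pattern is the set of 35 targeted-only peaks, of which MIR100HG is 1. The same signal hidden below the control library's threshold would put their ratios in the range of the shared peaks. In the authors' deposited table their median log2 ratio was 3.92, against at most 0.92 at shared peaks. Shared peaks were called in both libraries, which limits that range in advance, so it is not an independent standard. The raw reads do not use the range, and the 28 peaks with at least 2-fold more reads held a median of 158 targeted against 6.5 control reads. A hidden signal stays open for the 7 within that range, and for the 12 peaks given next, where it could act together with duplicates. Copies of a few molecules would not by themselves raise the depth-scaled ratio of distinct targeted fragments to all raw control reads. Its interval lay above 1 at 16 of the 28 peaks with at least 2-fold more reads, with a lower limit of 1.05 at TRIM32. Without the depth scaling the lower limits at TRIM32 and SYN2 would fall below 1. The 28 peaks were picked in the same 2 libraries and the intervals were not corrected for their number, so chance is not excluded. For the other 12 peaks copies stay open, since that setting lowers every ratio. A difference in depth would raise the shared loci as well, and their median raw read ratio was 1.07. Binding of dCas9 at partial matches of the guide may account for these peaks and stays open, as does a difference between the libraries unrelated to the guide. Neither was tested, and no match of the guide was sought at any peak.

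The second pattern is the low fold enrichment of the MIR100HG peak, 28 of 28 in rank, although the guide was directed at its locus. The margin of that last rank is small, with 5.37 against 5.38 at NNMT. The NNMT peak had a lower pileup (7 against 10) and a lower −log10 q (2.29 against 2.71). Loss of height through removal of duplicates as the whole cause would put it among the highest by raw reads, and its rank was 20. A part of it in the step from 20 by reads to 24 by pileup stays open. A high local background as the whole cause would put it among the highest by pileup, and its rank was 24; background accounts for the step to 28, since 4 peaks with no higher pileup had a higher fold enrichment. Lower occupancy of the target than of other sites, or less fragmentation or recovery of its chromatin, could explain the rank and was not tested. Counting variation at a pileup of 10, where the median of the 28 was 13, was not tested either and stays open.

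The third pattern is the number of raw reads per unit of pileup. Its median was 10.8 (1.5 to 16.5) at 33 of the 35 targeted-only peaks (1 summit, under 350 bp, pileup of at most 50). The pattern lies in the 27 of these with at least 2-fold more reads, where the median was 11.3. All 7 targeted-only peaks under 2-fold, parted from them by read number itself, had a median of 2.78 (1.5 to 19.5). The highest of the 7, 19.5, was at the ANKRD26P1 peak, which at 553 bp is outside the width limit. A higher duplicate rate throughout the targeted library would give its matched shared peaks as many, and 17 of them had a median of 5.90 (3.50 to 13.3). Reads placed at several repeat copies may count in the pileup and not in the read counts, which would lower the shared peaks. Among the 17, the 6 at genes of the repeats list had a median of 7.24 (4.55 to 13.3) and the other 11 a median of 5.60 (3.50 to 9.17). The files do not mark repeats, and the other 11 may lie in them too. If repeats lowered the shared peaks, those peaks cannot exclude a higher duplicate rate throughout the library. Placement at repeats, such a rate and a true difference in duplication at the targeted-only peaks therefore cannot be told apart.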
